A study of Mus musculus with 721 samples.

How the data were processed

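Single cells from mouse embryonic pancreata were the samples. Per the labels, each cell carried an eGFP reporter of Neurog3, was sorted for eGFP into a well of a 96-well plate, and was sequenced as a Nextera XT library of SMART-seq cDNA. SMART-seq copies whole polyadenylated transcripts without molecular identifiers, so fragments that are copies of 1 molecule cannot be told apart, and without strand marking reads of overlapping sense and antisense genes cannot be told apart either.

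The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments) for each gene and cell. Per the submitters' processing notes, TopHat2 2.0.13 and Cufflinks 2.2.0 were named with the genome build mm10, with no role or order, and the annotation the authors used is not given in the sources used here. The deposited FPKM values already hold a division by transcript length and by depth, and counts were not analysed here. The fragments per cell given here are the labels' values of total mass, read as Cufflinks' total of mapped fragments. The gene table held 32913 entries, of which 32806 were Ensembl genes and 107 were spike-ins, a vector and the reporter. All 721 columns were matched to cells by name, and 0 columns of values were left unmapped.

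Cells entered with at least 100000 fragments and at least 1500 genes at 1 FPKM or more, which kept 658 cells and left out 63. All deposited cells held 111 to 1990000 fragments, with a median of 555515. Each well was sorted to hold 1 cell, and no doublet caller was run. The labels name no animals and cells are not replicates, so each day in each sequencing run was treated as 1 cell set, with 8 sets in all. Shares of cells carry 95% exact Clopper-Pearson intervals, which cover counting error only. Files of the runs were compared for repeated cells, and the highest correlation between a cell of run 1 and a cell of run 2 was 0.622 at E13.5, 0.844 at E14.5 and 0.657 at E15.5. At E14.5 the next highest was 0.691, and the highest within a run 0.702 and 0.705, so 1 pair stood apart there. Whether that pair was 1 cell was left open, and every cell was kept as its own.

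Expression was compared on log2(mean FPKM over the cells of a set + 1), so a fold change is on that scale and understates the change of genes with low FPKM. Genes entered with a mean of at least 1 FPKM over the sets. The slope along embryonic day was fitted with limma 3.58.1 in R 4.3.3 (moderated linear model with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), with day and run as terms. Gene lists were tested with camera from limma, with a preset correlation between genes of 0.01 and with an estimated correlation beside it. The share of cells with a transcript at 10 FPKM or more (100 FPKM for both glucagon and insulin) was compared along day by an exact permutation test of days within runs.

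Cells were clustered with scanpy 1.11.5 and python-igraph 0.11.9 on log2(FPKM + 1) of 2000 variable genes, 20 principal components and 15 neighbours, with Leiden resolution 1 and seed 0. The 8 gene lists compared between classes were left out of the clustering. A cluster was named from fixed cell type markers when at least 3 of them were raised by a log2 difference of 1. Means of a class in a set needed at least 5 cells, and a fit along day within a class needed 6 sets. Classes were contrasted with limma with the set as a block, the slopes of Neurog3-high and alpha-like cells were compared as an interaction of day and class, and runs were compared over the 6 sets of E13.5 to E15.5 with day as a factor. The contrast of Neurog3-high with duct or trunk cells could not be fitted, since no cluster took that name.

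The tests, cell type markers, 14 gene lists and the rule for named genes were fixed before the data were examined. The rule named up to 12 rising and 12 falling genes past the test over all cells, up to 4 members of each list past the test or else the 2 with the largest slopes, up to 4 members per list and contrast between classes, up to 8 rising and 8 falling genes within a class, and 9 genes in every case, which were Neurog3, Sox9, Fev, Ins1, Ins2, Gcg, Sst, Ghrl and Ppy. Predicted genes were not named by the rule. Some genes that the rule takes are not reported here. The 8 other genes of the run comparison, Gm22133, and the marker genes given for clusters stand outside it or define clusters. Of the list members only the alias Hnf6 had no entry.

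Each fit was tested on simulated data with 200 changed genes. A slope of 2 log2 units per day was recovered for 91% of genes over all cells (16154 genes) and 23.9% in Neurog3-high cells (14880 genes). Between classes a difference of 4 was recovered for 75.8% to 86.4% of genes (15710 genes). Simulated genes need not share the spread of real ones, and 200 changed genes ease the adjusted threshold, so real genes may be recovered less often.

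The GC content and length of transcripts came from GENCODE vM21 on the same build as the files. Of 4344 genes with a mean of 20 FPKM or more, 4328 had a GC content (99.6%). Coordinates of 385 named or listed genes were taken from GENCODE, and of the 383 with a locus in the files all 383 overlapped it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

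Alternatives tried were pseudocounts of 0.1 and 10, no filter, the mean of log values per cell, rescaling each cell to the same total, no run term, single runs, 5 stage means, minimum depths of 300000 and 10000 fragments, other thresholds for shares, other cluster resolutions and gene numbers, run-centred clustering, quantile normalization, a depth covariate and each set left out in turn. Alternatives added after seeing the data were the exclusion of the acinar or tip-like, leukocyte-like and endothelium-like classes, E13.5 to E15.5 alone, the exclusion of the 2 sets low in GC-rich transcripts or of clusters 7 and 8, centring by GC content, rescaling without predicted, small RNA and mitochondrial genes, a sex covariate, E14.5 and E15.5 alone for the run comparison, and stage means for shares and for the fits within and between classes.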

Results

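Transcriptomes were measured in 721 single cells from the pancreata of mouse embryos that carried an eGFP reporter of Neurog3, the transcription factor that starts endocrine differentiation. Cells positive for eGFP were sorted one per well into 96-well plates, and full-length cDNA was sequenced with SMART-seq and Nextera XT libraries. The cells came from 5 embryonic days, of which the 3 later were sequenced in 2 runs and the 2 earlier in run 1 alone. This gave 8 cell sets of 1 day and 1 run each, with 79 cells at E11.5, 95 at E12.5, 72 and 93 at E13.5 (runs 1 and 2), 96 and 95 at E14.5, and 96 and 95 at E15.5. The labels name no animals, so the p-values measure only the spread between cell sets or between days, and both runs of a day may hold cells of the same embryos. After a minimum of 100000 fragments and 1500 detected genes per cell, 658 cells were kept, with 73 at E11.5, 90 at E12.5, 68 and 78 at E13.5, 94 and 85 at E14.5, and 88 and 82 at E15.5. The kept cells held 101675 to 1990000 fragments, with a median of 587177, and 1531 to 12309 genes at 1 FPKM or more, with a median of 5572. Median fragments per set ran from 480057 in E14.5 run 2 to 844416 in E13.5 run 1.

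Sets stood apart in transcript composition. GC-rich transcripts were low in 2 sets. Over 84 genes with a GC content above 60%, against 2007 genes with 40 to 50%, the median log2 level was lower by 1.48 in E12.5 run 1 (-1.48) and by 1.13 in E13.5 run 1 (-1.13), while the other 6 sets lay between -0.34 and 0.39. Rpl13, a ribosomal protein gene, measured 84.7 FPKM in E12.5 run 1 and 111 FPKM in E13.5 run 1, against 1143 to 2160 FPKM in the other sets. Predicted and small RNA genes took a median of 40.2% of the FPKM per cell in E13.5 run 2, 42.9% in E14.5 run 2 and 37.7% in E15.5 run 2, against 9.10% to 19.9% in the sets of run 1. Mitochondrial genes took 6.38% to 10.95%, with the 2 highest medians in the 2 sets low in GC-rich transcripts. Y-linked transcripts were present in over 90% of the cells of the E11.5, E12.5 and E15.5 sets, and Xist in over 90% of the cells of the E13.5 and E14.5 sets, no cell of which held Y-linked transcripts. Xist together with a Y-linked gene was seen in 8 cells.

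**Figure D1:**
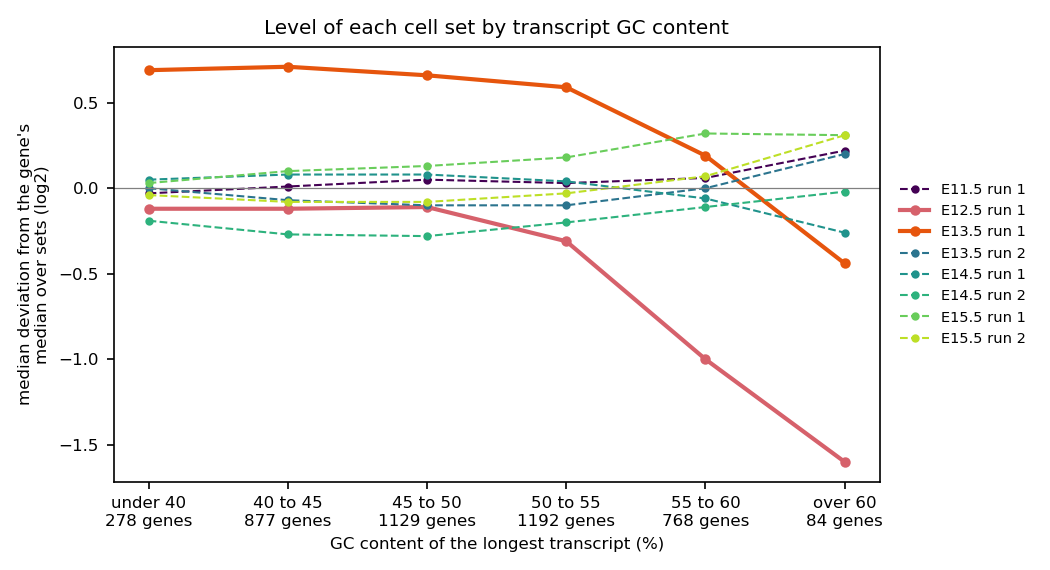
Median log2 deviation of each cell set from the gene's median over the 8 sets (vertical axis), for genes with a mean of 20 FPKM or more grouped by the GC content of their longest transcript (horizontal axis, %). E12.5 run 1 falls to -1.60 and E13.5 run 1 to -0.44 above 60% GC, where the other sets lie between -0.26 and 0.31.

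The reporter and its driver were read in each set as a check of the sort. Transcripts of eGFP at 1 FPKM or more were seen in 5.50% of cells at E11.5 (95% exact binomial interval 1.5 to 13.4%), in 0 of 90 cells at E12.5 (upper bound 4.0%), and in 17.6% to 46.2% of the cells of the later sets. Neurog3 at 10 FPKM or more was present in 13.7% of cells at E11.5 and 8.90% at E12.5, in 63.2% and 76.9% at E13.5 in runs 1 and 2, in 55.3% in both runs at E14.5, and in 51.1% and 50% at E15.5. By cell class (below), eGFP transcripts were found in 55% (47.6 to 62.2%) of Neurog3-high cells, 10.3% of 78 Fev-high cells, 3.60% of 110 alpha-like cells and 1.40% of 73 beta-like cells. They were found in 7 of 91 acinar or tip-like cells (7.7%, 3.1 to 15.2%), 0 of 42 leukocyte-like cells (upper bound 8.40%) and 0 of 13 endothelium-like cells (upper bound 24.7%). These intervals cover counting error only, and sorting read the protein while the files hold transcripts. The E12.5 set and E13.5 run 1 were low in GC-rich transcripts, and whether this lowered the eGFP shares there was not tested.

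Which cell types the sorted cells represented at each day was the next question. Clustering gave 12 clusters, of which 11 were named from the fixed markers. At E11.5 and E12.5 most sorted cells carried markers of acinar or tip cells, leukocytes or endothelium. Acinar or tip-like cells, with the digestive enzyme genes Cpa1 and Cel among their raised markers, made up 49.3% (37.4 to 61.3%) of cells at E11.5 and 52.2% (41.4 to 62.9%) at E12.5, and at most 3.40% in any later set. Cluster 2, which gave 45 of the 91 cells of this class and all 36 of those at E11.5, had 0 of its markers among its 10 leading genes. At E12.5, 45 of the 47 cells of this class lay in cluster 9 instead. Leukocyte-like cells, with Ptprc, Cd68 and the complement genes C1qa and C1qb, made up 26% and 24.4% at E11.5 and E12.5, and endothelium-like cells with Pecam1, Cdh5 and Kdr were 13 of the 90 cells at E12.5. Together these 3 classes, called the early classes here, held 75.3% (63.9 to 84.7%) of cells at E11.5 and 91.1% (83.2 to 96.1%) at E12.5, and 0 to 3.70% per set from E13.5 on.

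From E13.5 most cells lay in endocrine classes. Neurog3-high progenitor-like cells were 48.5% and 53.8% of the E13.5 sets, 38.3% and 35.3% at E14.5, and 36.4% and 18.3% at E15.5 (runs 1 and 2). Beta-like cells, with the insulin genes, Iapp and the glucose transporter gene Slc2a2, were seen in no set through E13.5 (upper bounds per set of 4.0 to 5.3%), although run-centred clustering placed 1 and 7 cells of the E13.5 sets in that class and clustering of cells with at least 300000 fragments 1 in each. They made up 6.40% and 14.1% at E14.5, and 34.1% and 30.5% at E15.5. Fev-high precursor-like cells, named for the serotonergic transcription factor Fev, ranged from 0 to 5.50% in the E11.5, E12.5 and E13.5 run 1 sets and from 3.40% to 29.8% in the rest. Alpha-like cells ranged from 7.80% to 22% except in E13.5 run 1, where they were 48.5%, or 33 cells. Of these 33 cells, 28 lay in a Fev-high class at Leiden resolution 0.5, 27 with genes centred within runs and 26 with cells of at least 300000 fragments, while 33 stayed alpha-like at resolution 2 and 31 with 1000 variable genes. Pax4, a fixed Fev-high marker, averaged 764 FPKM in them, against 0.845 to 98.3 FPKM in alpha-like cells of other sets. In E13.5 run 1 as a whole, 32.4% of cells held Fev at 10 FPKM or more, against 30.7% to 41.5% in the other sets from E13.5. Gcg was there in 6 of 68 cells. The 0% Fev-high and 48.5% alpha-like shares of this set thus rest on the clustering. Of the 110 alpha-like cells, 50.9% held Gcg at 10 FPKM or more, so the class includes cells below that level. An unnamed cluster of 60 cells had a median depth of 0.4 times that of its sets. No cluster was named duct or trunk, so the planned contrast of Neurog3-high with duct cells was not estimable.

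**Figure D2:**
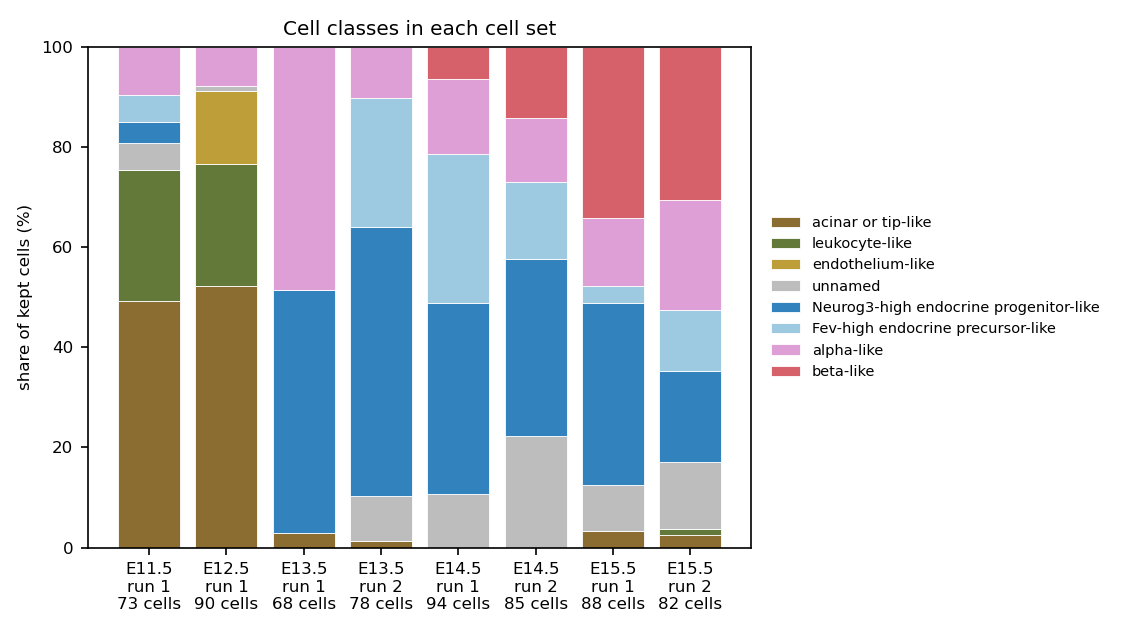
Share of kept cells (vertical axis, %) in each of 8 cell classes for the 8 cell sets (horizontal axis). The acinar or tip-like, leukocyte-like and endothelium-like classes fill 75.3% and 91.1% of the E11.5 and E12.5 bars, and beta-like cells appear at E14.5 and E15.5.

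The class shares were compared along day with an exact two-sided permutation test of days within runs (720 arrangements). No class passed after adjustment over the 7 named classes. The beta-like share had the lowest p, with a slope of 8.75 percentage points per day (exact p = 0.0167, adjusted p = 0.117), 5.72 without E15.5 run 1, and on 5 stage means 7.48 points per day (exact adjusted p = 0.35). With no beta-like cell through E13.5, the tied values made the exact p of 0.0167 the smallest possible over the 8 sets. The share could not pass on its own p there or on stage means, so not passing says little. It passed with cells of at least 300000 fragments (11.2, exact adjusted p = 0.0392) and with run-centred clustering (11.7, exact adjusted p = 0.0448). Both settings placed beta-like cells in the E13.5 sets, so fewer values were tied and a smaller p was possible. Cluster names rest on the rebuilt clustering and on how runs were treated, since with genes centred within runs the Fev-high class was found in run 1 alone. Clusters 7 and 8, which held 28 and 29 of the 68 cells of E13.5 run 1, a set low in GC-rich transcripts, gave most of the alpha-like and Neurog3-high cells of that set.

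The hormone genes give a view of differentiation that does not rest on clusters. Cells with Ins1 or Ins2, the 2 mouse insulin genes, at 10 FPKM or more made up 4.10% at E11.5 and 4.40% at E12.5, 3 and 4 cells. Their share was 11.8% and 7.70% at E13.5, 16% and 24.7% at E14.5, and 59.1% and 56.1% at E15.5 in runs 1 and 2. This share rose by 14.2 percentage points per day over the 8 sets (exact permutation p = 0.0028, adjusted p = 0.0224 over 8 shares). Among cells outside the 3 early classes, of which 18 remained at E11.5 and 8 at E12.5, it was 8.38 points per day and did not pass (exact permutation p = 0.2083, adjusted p = 0.556). With fewer units this share could not pass on its own p. On 5 stage means, with the day as the unit, the slope was 12.3 points per day (exact p = 0.0167, the smallest that 120 orders allow, adjusted p = 0.134). Without the 2 sets low in GC-rich transcripts it was 13.9 points per day (exact adjusted p = 0.296, where the smallest that this share alone allows is 0.222). With 1 set left out the smallest exact adjusted p on its own was 0.0552 to 0.111. The slope was then 18.9 without E11.5, 14.1 without E12.5, 14.2 without E13.5 run 1 and 13.1 without run 2, 16.2 without E14.5 run 1 and 14.2 without run 2, and 9.98 without E15.5 run 1 and 12.4 without run 2. The exact permutation p was the smallest possible in 7 of these 8 cases, and 0.0417 against a smallest of 0.0069 without E12.5. The adjusted p was 0.0445 without E13.5 run 2, where Gcg and Ghrl also passed, and 0.0552 to 0.256 in the rest (exact permutation tests).

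The other hormones did not pass. Sst, which encodes the delta-cell hormone somatostatin, was in 0 to 3.50% of cells through E14.5 and in 20.5% and 8.50% at E15.5 (slope 3.89 points per day, exact permutation adjusted p = 0.133). Gcg, the glucagon gene, was in 8.80% of cells of E13.5 run 1 and 30.8% of run 2 at the same day, with a slope of 1.27 points per day. Ghrl (ghrelin) and Ppy (pancreatic polypeptide) had slopes of 3.68 and 3.41, Fev 7.67, and Neurog3 7.87 points per day, and the lowest exact adjusted p of these 4 was 0.133. Without E13.5 run 2, Gcg (2.77 points per day) and Ghrl (4.62) passed (exact adjusted p = 0.0445 each). Without E15.5 run 1 the slope was 1.07 for Sst and -0.49 for Gcg, and without E11.5 it was 4.64 for Neurog3. Outside the 3 early classes the slope was -6.4 for Gcg, -0.12 for Ghrl, -1.63 for Ppy, 3.33 for Sst, 3.94 for Fev and 4.9 for Neurog3, and none passed. Cells with both glucagon and an insulin gene at 100 FPKM or more numbered 2, 1, 1, 7 and 6 at the 5 days. The counts would be 0.14, 0.20, 0.65, 2.11 and 5.06 if the transcripts were independent among all kept cells of a day. These expected counts pool endocrine and other classes, which alone can put the observed counts above them. The share of cells with both hormones had a slope of 0.77 points per day (exact permutation adjusted p = 0.144), 1.28 without E11.5 and -1.54 outside the 3 early classes.

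**Figure D3:**
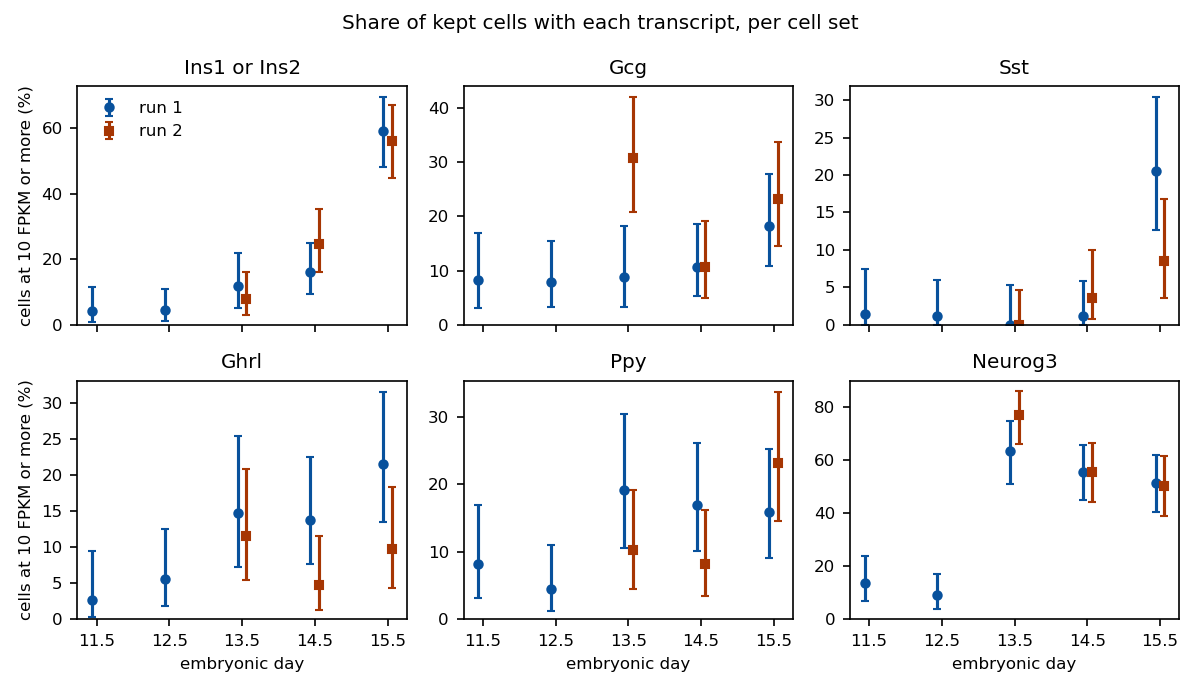
Share of kept cells at 10 FPKM or more (vertical axes, %) by embryonic day for 6 transcripts, with circles for run 1, squares for run 2 and bars for 95% exact binomial intervals. Insulin transcripts reach 59.1% and 56.1% of cells at E15.5, and Neurog3 is in 8.90% to 13.7% of cells before E13.5 and in 50% to 76.9% from then on.

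Expression was next compared along day over all kept cells, on the mean FPKM of each set. Lists of hormone and granule genes had positive and the cell cycle list negative mean slopes, while 0 of 16154 genes passed and none of these lists held with an estimated correlation (adjusted p = 0.0723, 0.141 and 0.112). The early classes made up 75.3% and 91.1% of cells at the first 2 days, and without them the cell cycle list had a mean slope of -0.038. The hormone and islet peptide list had a mean slope of 1.69 log2 units per day with all 12 members positive, led by Ins2 (3.76 ± 0.57 SE, from 5.45 FPKM at E11.5 to 21110 and 43010 FPKM at E15.5) and Ins1 (2.87 ± 0.57). Genes of hormone processing and secretory granules followed with a mean slope of 0.76 and 29 of 29 members positive, among them the granule zinc transporter gene Slc30a8 (1.68 ± 0.17) and Sytl4, a granule docking gene (1.41 ± 0.24). The cell cycle list had a mean slope of -0.81 with 0 of 34 members positive, including Ube2c, which drives mitotic protein degradation (-1.49 ± 0.26), and the survivin gene Birc5 (-1.26 ± 0.35).

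No gene passed over all 16154 tested by limma, while 1914 had an unadjusted p under 0.05 (766 rising and 1148 falling), and Slc30a8 had the lowest adjusted p, 0.132. Adjusted over the list alone, 7 hormone, 15 granule, 3 glucose sensing and 32 cell cycle genes passed, against 0 over all genes. By camera with a preset correlation 9 of 14 lists passed: hormones (adjusted p = 2.58e-11), endocrine transcription factors (3.41e-08), granules (5.78e-19), glucose sensing (2.78e-04) and the unfolded protein response (3.15e-04) rose, and cell cycle (1.70e-29), epigenetic factors (2.53e-04), ribosomal proteins (0.00979) and trunk factors (0.0462) fell. None held with an estimated correlation. The adjusted p with an estimated correlation was 0.0723 for hormones and for epigenetic factors, 0.112 for cell cycle, 0.141 for granules and for glucose sensing, 0.281 for trunk factors, 0.328 for endocrine factors, 0.466 for the unfolded protein response and 0.617 for ribosomal proteins. The trunk call was lost without any 1 set other than E15.5 run 2 (adjusted p = 0.0514 to 0.256), and the ribosomal call without E12.5 (0.0604), E14.5 run 1 (0.0697) or E15.5 run 1 (0.293). Without E11.5, immediate-early genes passed by camera with a preset correlation (0.35, adjusted p = 0.0300) and the count of single genes was 1.

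Within these lists, Neurog3 had a slope of 1.12 ± 0.45 and Pax4, a beta and delta lineage factor, 1.00 ± 0.51, while over E13.5 to E15.5 they had -0.16 and -0.83 and in run 2 alone -0.39 and -0.88. Among trunk and multipotent factors, Myc (-1.19 ± 0.28, and 0.028 in run 2 alone) passed over the list alone, and Onecut1 had a slope of -0.67 ± 0.27. Of the glucose sensing genes, G6pc2, an islet glucose-6-phosphatase (1.42 ± 0.20), and the incretin receptor gene Gipr (0.89 ± 0.26, and -0.0036 over E13.5 to E15.5) passed over the list alone. So did Uhrf1, which maintains DNA methylation (-1.23 ± 0.15), and Hmga2, a fetal chromatin protein gene (-0.69 ± 0.18), of the epigenetic list. Endocrine factors averaged 0.49, the unfolded protein response 0.24, epigenetic factors -0.24, trunk factors -0.21 and ribosomal proteins -0.083 log2 per day. The unfolded protein response mean was 0.53 without E11.5, 0.15 without E12.5, 0.12 without E15.5 run 1 and 0.13 without the 2 sets low in GC-rich transcripts. Endocrine factors had 0.32 without E12.5, trunk factors -0.11 without E11.5, and ribosomal proteins -0.054 without E14.5 run 1. Sdf2l1 and Creld2, chaperone genes of the endoplasmic reticulum, had slopes of 0.62 ± 0.57 and 0.53 ± 0.36 and were lowest in the 2 sets low in GC-rich transcripts. In the ribosomal list Rpl13 had a slope of 0.26 ± 0.45 and Rpl37 of -0.20 ± 0.13, which was 0.17 without the 3 early classes.

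The 5 lists that did not pass were Notch (-0.052), adhesion (-0.021), axon guidance (-0.088), imprinted genes (-0.017) and immediate-early genes (0.099). In them Dner (0.67 ± 0.17), Jag1 (-0.60 ± 0.23), Zeb2 (-0.80 ± 0.26), Cdh3 (-0.57 ± 0.13), Nrp1 (-0.83 ± 0.22), Crmp1 (-0.71 ± 0.25), Nnat (1.16 ± 0.42), Btg2 (0.67 ± 0.32) and Ier3 (-0.43 ± 0.41) had the largest slopes and passed on neither scale. Over E13.5 to E15.5 Zeb2 (0.040), Btg2 (-0.41) and Ier3 (1.03) had the other sign, and so had Cdh3 (0.34) and Ier3 (0.85) without the 3 early classes. Igf2, the imprinted growth factor gene (-0.99 ± 0.15), passed over its list alone. Of genes named in every case, Fev had 0.79 ± 0.25, Gcg 0.61 ± 0.29, Ghrl 1.77 ± 0.45, Ppy 0.86 ± 0.24, Sst 2.58 ± 0.61 and Sox9, a progenitor factor, -0.40 ± 0.19 log2 per day. Sox9 had 0.13 over E13.5 to E15.5, and Gcg -0.0060 without the 3 early classes. Ghrl had 2.10 in run 1 alone and 0.096 in run 2 alone, which holds E13.5 to E15.5. It measured 6757 FPKM in run 1 against 91.8 in run 2 at E14.5, and 9120 against 662 FPKM at E15.5.

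The share of the 3 early classes moved with the same lists, since it was 75.3% and 91.1% at the first 2 days and at most 3.70% later. Without those cells, which left 18 cells at E11.5 and 8 at E12.5, the hormone list had a mean slope of 1.27 (camera adjusted p = 1.17e-05, 0.150 with an estimated correlation), granules 0.39, glucose sensing 0.33 and the unfolded protein response 0.32. The cell cycle list had -0.038 with 20 of 34 members negative, and ribosomal proteins reversed to 0.20, while the median of all genes was 0.12. The endocrine factor, trunk and epigenetic calls were lost (adjusted p = 0.393, 0.592 and 0.139), and immediate-early genes rose (0.47, adjusted p = 4.81e-04, 0.264 with an estimated correlation). Over E13.5 to E15.5 alone, hormones had a mean slope of 2.17, cell cycle genes -0.39 (camera adjusted p = 2.00e-05, 0.495 with an estimated correlation) and endocrine factors 0.0072. On 5 stage means the hormone list had 1.57 (adjusted p = 0.320 with an estimated correlation) and the cell cycle list -0.93 (0.320). Without the 2 sets low in GC-rich transcripts the values were 1.54 and -0.72, and the trunk list no longer passed (adjusted p = 0.147). Orders of the 5 days gave a slope as far from 0 for the hormone and cell cycle lists in 4 of 120 cases each (exact permutation p = 0.0333, adjusted p = 0.117).

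**Figure D4:**
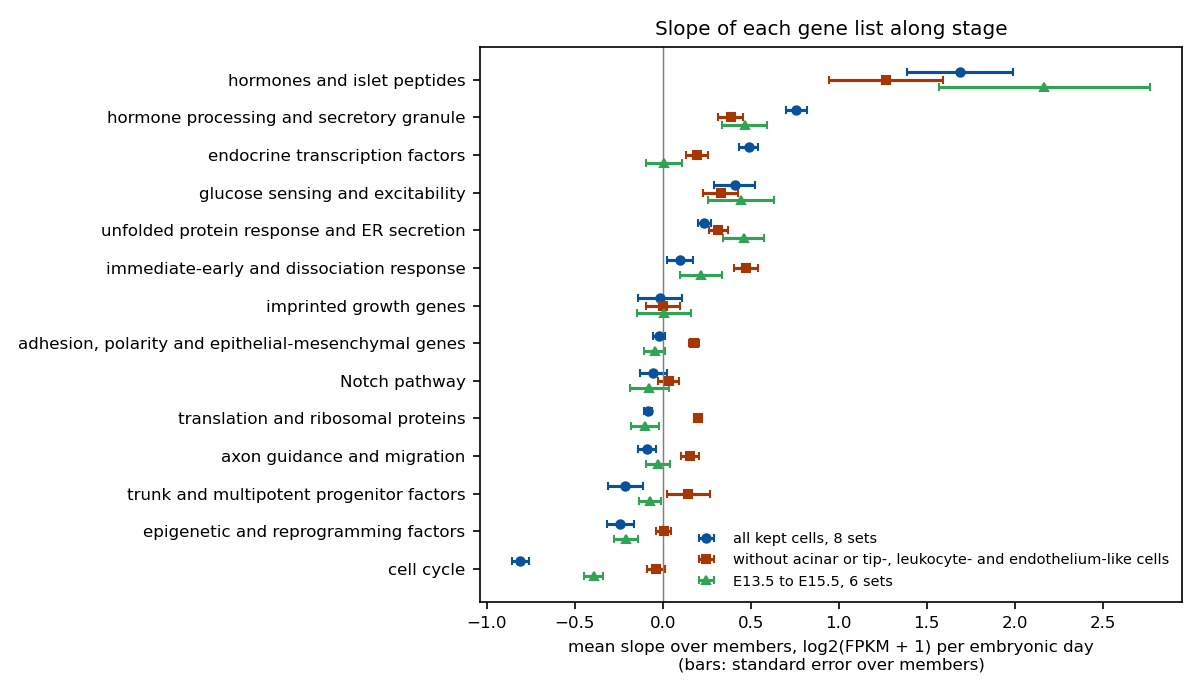
Mean slope of each of 14 gene lists over its members (horizontal axis, log2(FPKM + 1) per embryonic day, bars for the standard error over members), for all kept cells (circles), without the 3 early classes (squares) and for E13.5 to E15.5 (triangles). The cell cycle list lies at -0.81, -0.038 and -0.39, and the hormone list at 1.69, 1.27 and 2.17.

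In GENCODE vM21 coordinates on mm10, the build of the files, the genes named in every case lie as protein-coding genes at chromosome 10, 62133090 to 62134763 (Neurog3), chromosome 11, 112782224 to 112787760 (Sox9), and chromosome 1, 74881509 to 74885419 (Fev). The hormone genes lie at chromosome 19, 52264297 to 52265476 (Ins1), chromosome 7, 142678656 to 142743381 (Ins2), chromosome 2, 62474530 to 62483650 (Gcg), chromosome 16, 23889573 to 23890958 (Sst), chromosome 6, 113716119 to 113719880 (Ghrl) and chromosome 11, 102099930 to 102101319 (Ppy). The files measured whole genes, so no exon or UTR was singled out. The Ins2 locus of the files ended at 142699510, and the Neurog3 locus ran from 62107655 to 62143920.

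Mean profiles of a class were compared between days, which sets aside the class shares but not a shift in the mix of cells within a class. In alpha-like cells, present in all 8 sets, the hormone list had a mean slope of 0.92 with 11 of 12 members positive (adjusted p = 0.176 with an estimated correlation). Of its members 6 passed over the list alone against 0 over all genes, with Iapp, the islet amyloid polypeptide gene, at 1.76 ± 0.26. Sst had 2.38 ± 0.60, and 6 of the 110 alpha-like cells held it at 10 FPKM or more. Its mean was 4434 FPKM in E15.5 run 1, 2.47 FPKM in E15.5 run 2 and 0 to 74.9 FPKM in the other sets. Granule genes had a mean slope of 0.33 with 26 of 30 positive, led by Slc30a8 (1.40 ± 0.26) and the granin gene Scg2 (0.89 ± 0.20), and 5 passed over the list alone. The cell cycle list had -0.20 with 7 of 25 members positive, and Gcg itself had 0.37 ± 0.30. The class was mixed, with Ghrl in 24.5% and insulin transcripts in 36.4% of its cells at 10 FPKM or more. Its mean Ghrl ran from 96.6 FPKM in E14.5 run 2 to 20145 FPKM in E15.5 run 1. A changing mix of cells was not separated from a change within alpha cells.

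No gene of 14733 passed by limma in alpha-like cells (1217 at an unadjusted p under 0.05, 1014 rising and 203 falling, lowest adjusted p 0.135). By camera the hormone (adjusted p = 1.70e-05), granule (4.18e-04), cell cycle (1.73e-04), ribosomal (0.0200) and Notch (0.0329) lists passed with a preset correlation. None did with an estimated correlation, where the adjusted p was 0.176 for hormones, 0.414 for granules and cell cycle, 0.666 for Notch and 0.865 for ribosomal proteins. The median of all genes had a slope of 0.12 here and 0.0085 with each cell rescaled to the same total. Camera ranks a list against all genes, and it pointed down for the endocrine factor, guidance, imprinted and epigenetic lists although their mean slopes lay above 0. E13.5 run 1 gave 33 of the 110 alpha-like cells, more than any other set and mostly Fev-high with 3 other clusterings, and without it and E12.5 run 1 the count was 1 gene, as it was without E11.5.

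In Neurog3-high progenitor-like cells, present in the 6 sets from E13.5, granule genes had a mean slope of 0.33 with 20 of 27 positive. They included Scg2 (2.35 ± 0.64) and the chromogranin gene Chga (1.47 ± 0.34). Scg2 differed between the runs of a day, with 39.25 FPKM in run 1 and 0.0 FPKM in run 2 at E14.5. At E15.5 it measured 85.995 FPKM in run 1 and 14.382 FPKM in run 2. Mean Ghrl in this class was also higher in run 1 than in run 2 at both days. Whether cells with Ghrl in the class gave the Scg2 slope was not tested. Chga measured 45.3 FPKM in E13.5 run 1, a set low in GC-rich transcripts, and 248 FPKM in run 2 of that day. List slopes in this class were not computed without that set. The cell cycle list had -0.45 with 3 of 34 positive, including the anaphase activator Cdc20 (-1.16 ± 0.37), and endocrine factors had 0.20, with Hhex at 1.47 ± 0.49 and Runx1t1 at 1.08 ± 0.32. By limma 0 of 14880 genes passed (1269 at an unadjusted p under 0.05, 377 rising and 892 falling, lowest adjusted p 0.233), and 0 members passed over any list alone. Camera called these 3 lists (adjusted p = 7.92e-04, 0.0165 and 0.0130), and each had an adjusted p of 0.713 with an estimated correlation. Different clusters held most of the class by set, with 29 of 33 cells of E13.5 run 1 in cluster 8, 25 of 42 of E13.5 run 2 in cluster 4 and 25 of 32 of E15.5 run 1 in cluster 6, and without clusters 7 and 8 the count was also 0. The median of all genes had a slope of -0.11, which rescaling each cell to the same total removed. Camera pointed up for the adhesion, guidance, trunk and imprinted lists although their means lay below 0, and the unfolded protein response list had a mean of 0.070 and a median of -0.037. With the mean of log values 1.0% of the tested genes passed, 22 of them rising, in run 1 alone 3.81%, 330 of them rising, and on stage means 8 genes, 2 of them rising. Fev-high and beta-like cells filled 4 sets each, too few for this fit.

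The classes were then compared within sets, on 210 members of the 8 lists kept out of the clustering. Only the listed genes were kept out. Other genes of the same programmes could enter the clustering, so classes may differ in list members partly because of how cells were grouped. Peg10 was also a fixed alpha marker used in naming clusters. Between Neurog3-high and Fev-high cells, cell cycle genes were lower in Fev-high cells, with a mean difference of -1.79 and 0 of 28 members higher. Examples were the replication helicase genes Mcm3 (-4.22 ± 0.80, 4.29 against 75.4 FPKM) and Mcm5 (-3.29 ± 0.78), Cdc20 (-3.26 ± 0.67) and cyclin B2, Ccnb2 (-3.02 ± 0.66). The Notch ligand gene Dll1 (-3.71 ± 0.72) and Hes6 (-1.60 ± 0.33), and the adhesion list members Snai2 (-3.38 ± 0.45), Snai1 (-2.49 ± 0.56) and Cdh3 (-3.20 ± 0.43), were also lower, while the intermediate filament gene Vim was higher (3.06 ± 0.73). Of 18 imprinted genes 8 were higher and 1 lower in Fev-high cells over all genes, against 9 and 1 adjusted over the list alone (list adjusted p = 0.0807 with an estimated correlation). They included Peg10 (3.53 ± 0.50), Gnas (2.01 ± 0.17) and Snrpn (1.70 ± 0.35), with H19 the one lower (-3.45 ± 0.53). Fos (2.34 ± 0.48), Map1b (0.82 ± 0.20), Sec61b (1.03 ± 0.20) and Spcs1 (0.77 ± 0.20) were higher, and Nrp1 (-2.25 ± 0.61) and Rps19 (-0.79 ± 0.15) lower.

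In this contrast 16 members were higher and 17 lower in Fev-high cells by limma over all genes, and all 20 genes named had their direction in 4 of 4 shared sets. Cell cycle genes passed in 7 cases over all genes and in 16 adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.00284). Notch, imprinted and ribosomal lists passed with a preset correlation (0.00401, 8.28e-04 and 4.04e-07), and had adjusted p values of 0.0807, 0.0807 and 0.223 with an estimated correlation. The ribosomal mean of -0.26 was -0.16 without E13.5 run 2. On stage means 6 members were higher and 11 lower and the cell cycle list held (-1.87, adjusted p = 0.00345 with an estimated correlation). The count was 21 without E13.5 run 2, 16 without E14.5 run 1, 13 without E14.5 run 2 and 14 without E15.5 run 2, and 31 without the 2 sets low in GC-rich transcripts. With run-centred clustering, where the Fev-high class was found in run 1 alone, 7 members were higher and 9 lower. The median of all genes was 0.17, and with each cell rescaled to the same total it was 0.025, with 14 members higher and 36 lower.

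Between alpha-like and Fev-high cells 9 members passed by limma, 2 of them immediate-early genes, which respond to stimulation and to tissue dissociation. The immediate-early list was the only one of the 8 to hold with an estimated correlation (adjusted p = 0.0236, and 0.134 on stage means). Its mean difference was -1.64 with 1 of 14 members higher in alpha-like cells, and Jun (-3.10 ± 0.68) and Btg2 (-2.37 ± 0.35) were lower. Vim (-4.67 ± 0.73), Sema6a (-2.38 ± 0.51) and the neuronal tubulin gene Tubb3 (-2.17 ± 0.37) were lower, and N-cadherin, Cdh2 (3.45 ± 0.71), and Zeb1 (2.32 ± 0.46) higher. Ribosomal Rpl28 (-0.62 ± 0.15) was lower. Of the 9 members 2 were higher and 7 lower, each in the same direction in 4 of 4 shared sets, and over the lists alone 9 immediate-early and 14 ribosomal genes were lower. The ribosomal (-0.39) and unfolded protein response (0.26) lists passed only with a preset correlation (adjusted p = 0.345 and 0.712 with an estimated correlation). The cell cycle, adhesion, guidance and imprinted lists had means, medians or tests of different sign and did not pass. Averaged by day the counts were 0 higher and 2 lower and the immediate-early list had -1.62. The count was 5 without E13.5 run 2, 1 without E14.5 run 1, 3 without E14.5 run 2, 4 without E15.5 run 1 and 0 without E15.5 run 2, with 5 higher and 10 lower after rescaling and 5 higher and 5 lower with run-centred clustering. The unfolded protein response call was lost without E13.5 run 2 (0.065, adjusted p = 0.489) and without E14.5 run 1 (0.23, 0.0905), and its mean was 0.48 without E14.5 run 2.

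Between Fev-high and beta-like cells the unfolded protein response, ribosomal and immediate-early lists passed with a preset correlation only (adjusted p = 0.148, 0.154 and 0.0527 with an estimated one), and the 21 members past limma came to 1 on stage means and 0 with run-centred clustering. The unfolded protein response list had a mean difference of 0.78 with 19 of 25 members higher, and Sdf2l1 (2.89 ± 0.62), the disulfide isomerase gene Pdia6 (1.45 ± 0.35) and calreticulin, Calr (1.30 ± 0.30), passed. Ribosomal and translation genes had a mean of -0.53 (0 of 24 higher), with Eef2 (-0.89 ± 0.19), Eif4a1 (-0.79 ± 0.19) and Rpl5 (-0.77 ± 0.16) lower. Immediate-early genes had a mean of -1.65 (0 of 14 higher), with Egr1 (-3.35 ± 0.65), Btg2 (-2.79 ± 0.39) and Zfp36 (-2.66 ± 0.64) lower. The imprinted gene Nnat was higher (3.61 ± 0.71) and Grb10 (-1.60 ± 0.32), Sgce (-1.60 ± 0.35) and Peg3 (-1.33 ± 0.26) lower, as were Muc1 (-3.88 ± 0.71), Dll4 (-2.42 ± 0.54) and Mcm7 (-2.69 ± 0.60).

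By limma 4 members were higher and 17 lower in beta-like cells, in 3 of 3 shared sets for each gene named, with a median difference of -0.26 over all genes. With each cell rescaled to the same total the median was -0.086, with 9 members higher and 8 lower. Over the lists alone 8 unfolded protein response genes were higher and 18 ribosomal and 9 immediate-early genes lower. Without E14.5 run 1, E14.5 run 2, E15.5 run 1 or E15.5 run 2 the counts were 1, 1, 4 and 2, and the unfolded protein response mean was 0.50 without E15.5 run 2.

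Between alpha-like and beta-like cells 6 members passed by limma, 3 of them imprinted genes, while the imprinted list did not pass camera (adjusted p = 0.0816) and the count was 0 on stage means or with run-centred clustering. Nnat was lower in alpha-like cells (-4.11 ± 0.64, against 3020 FPKM in beta-like cells), and Sgce (2.76 ± 0.31) and Peg3 (1.25 ± 0.24) were higher. Cyclin E1, Ccne1 (-3.49 ± 0.66), Tubb3 (-2.22 ± 0.37) and the translocon gene Sec61b (-1.04 ± 0.20) were lower, each in 4 of 4 shared sets. Of the 6 members 2 were higher and 4 lower. Over the lists alone 9 imprinted genes were higher and 3 lower, and 3 unfolded protein response genes were lower. The unfolded protein response list passed camera with a preset correlation (-0.51, adjusted p = 3.88e-07, 0.580 with an estimated correlation, mean -0.30 without E15.5 run 2), and the Notch and immediate-early lists had means and tests of different sign and did not pass. The count was 2, 1 and 2 without E14.5 run 1, E14.5 run 2 and E15.5 run 2.

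**Figure D5:**
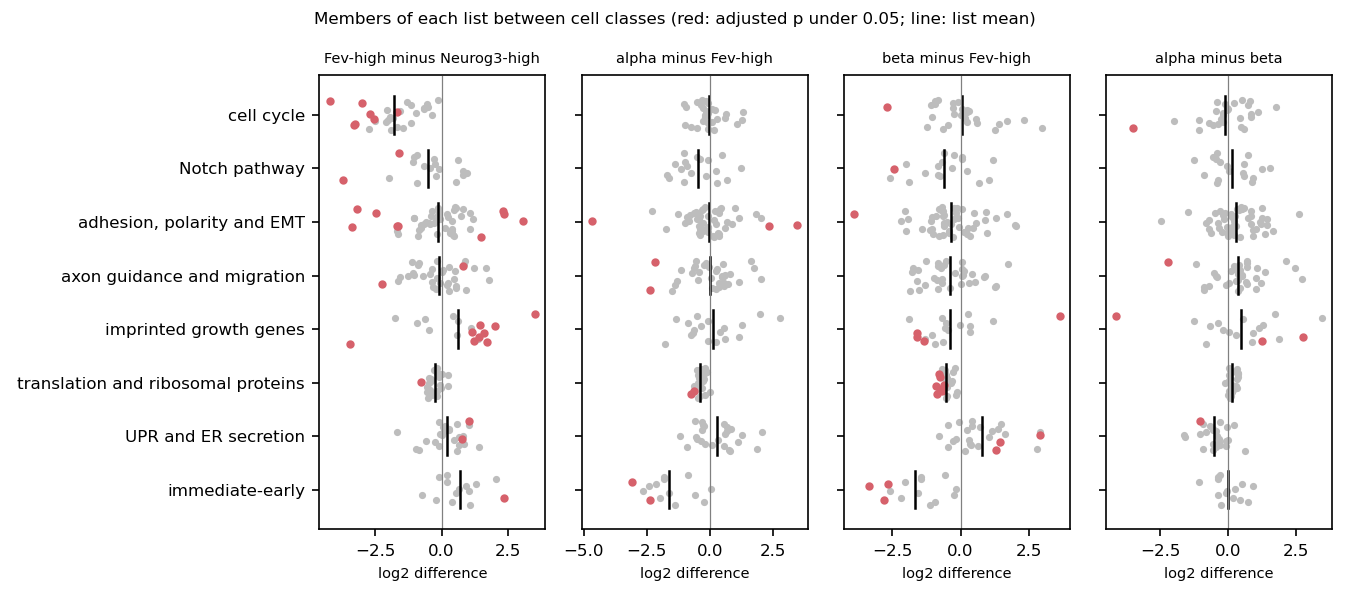
Log2 difference between cell classes (horizontal axes) for each member of the 8 lists left out of the clustering (vertical axis), in 4 contrasts, with members past an adjusted p of 0.05 in red and list means as black lines. In Fev-high minus Neurog3-high the cell cycle mean lies at -1.79, and the immediate-early mean lies at 0.69 there, at -1.64 in alpha-like minus Fev-high and at -1.65 in beta-like minus Fev-high.

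Whether the slope along day differed between Neurog3-high and alpha-like cells was tested as an interaction. By limma 0 of 15548 genes passed, with 960 at an unadjusted p under 0.05. On stage means 1 gene passed, without E15.5 run 1 also 1, and with means of log values 2. The median difference of slopes over all genes was -0.15, and rescaling each cell to the same total removed it.

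The 3 days that were sequenced in 2 runs allowed a comparison of the runs. Of 15743 genes 98 were higher and 14 lower in run 2 by limma with day as a factor, and all but 8 of them had names of predicted or small RNA genes. Gm22133 was at 1 FPKM or more in 241 of 245 cells of run 2 and in 2 of 413 of run 1, with a median of 107750 FPKM in run 2. The 8 with other names, all higher in run 2, among them 3 entries for parts of the long non-coding RNAs KCNQ1OT1, MIAT and FTX, were Lars2, the mitochondrial leucyl-tRNA synthetase gene (2.10 ± 0.21, 21.9 against 98.4 FPKM), Snurf (3.58 ± 0.24), Stab1 (3.00 ± 0.32), KCNQ1OT1_3 (8.45 ± 0.26), AF357399 (4.27 ± 0.34), Igkv13-87 (3.98 ± 0.35), MIAT_exon5_1 (4.32 ± 0.42) and FTX_3 (4.58 ± 0.47). The median of all genes was -0.098, and -0.23 with each cell rescaled to the same total. The count was 9, all higher in run 2, with each cell rescaled over genes other than predicted, small RNA and mitochondrial ones (median 0.19). This setting left genes with predicted and small RNA names, most of the called ones, out of the 14039 genes tested, and 7 of the 8 with other names passed in it. The count was 130 over the 4 sets of E14.5 and E15.5.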

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

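The tests weighed here were chosen after the results were seen, except the tests of the order of the days and of transcript length, which were written before.

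Signals lay outside the main measurement in 6 entries. The ERCC vector sequence was at 1 FPKM or more in 50 cells, and 4 RNA spike-in sequences were in 2, 2, 7 and 2 cells, although the labels describe no spike-in. Gm22133, a predicted gene, was in 241 of the 245 kept cells of run 2 and in 2 of the 413 kept cells of run 1, and it took a median of 11.38% of the FPKM per cell in run 2.

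Acinar or tip-like, leukocyte-like and endothelium-like cells filled 75.3% and 91.1% of the eGFP-sorted cells at E11.5 and E12.5. Wells that also held a Neurog3-high cell were argued against for most leukocyte-like and most acinar or tip-like cells. Of the leukocyte-like cells 3 of 42 (7.1%, upper bound 19.5%) held 10 FPKM or more of Neurog3, Chga or Chgb. Of the acinar or tip-like cells 30.8% did (upper bound 41.3%), against 98.4% of Neurog3-high cells. That class was named by markers that include Neurog3, and it held 3 cells at E11.5 and 0 at E12.5. For alpha-like cells, of which 24.5% held Neurog3, the share with any of these genes was not computed. Wells with other endocrine cells therefore stayed open. Low depth was argued against by a ratio of 1.06 between the median fragments of these cells and of other cells in both sets. Reporter transcripts were rarer than in Neurog3-high cells, where the lower bound was 47.6%. They were in 0 of 55 leukocyte-like and endothelium-like cells (upper bound 6.5%) and in 7 of 91 acinar or tip-like cells (7.7%, upper bound 15.2%). Of these cells 22 leukocyte-like, all 13 endothelium-like and 47 acinar or tip-like ones came from E12.5. There GC-rich transcripts were low, eGFP was in 0 of 90 cells and no Neurog3-high cell was found. Class and set cannot be separated for those cells, so this cannot decide on their reporter transcription at sorting. Whether Neurog3, Chga and Chgb were also lowered in that set was not tested. Lower transcription in acinar or tip-like cells also stayed open. A wider sorting gate at the early days, autofluorescence, and a difference of the tissue between days stayed open and were not tested.

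Over all cells the cell cycle list had a negative and the hormone list a positive mean slope along day. The loss of the 3 early classes may account for the cell cycle slope over E11.5 to E15.5, which was -0.038 without them, while over E13.5 to E15.5 alone the slope of -0.39 had an adjusted p of 0.495 with an estimated correlation and cannot be told apart from no change relative to other genes. For hormones the slope without these cells was 1.27, on 18 cells at E11.5 and 8 at E12.5. It did not pass by camera with an estimated correlation, nor did the insulin share outside these classes (exact permutation p = 0.2083). So this slope cannot decide whether their loss was the whole cause over E11.5 to E15.5. Over E13.5 to E15.5, where these classes held at most 3.7% of a set, the hormone slope was 2.17, which their loss could hardly give. The sex of the sets was argued against for the cell cycle, since among sets with Y-linked transcripts E15.5 run 1 lay at -2.90 log2 units from the lower of E11.5 and E12.5. As large a slope came from 4 of 120 orders of the days for either list (exact permutation p = 0.0333 each, adjusted p = 0.117 over 14 lists), and maturation with age stayed open.

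The genes that differed between runs mostly had names of small and predicted RNA genes. A few abundant entries taking FPKM from the rest would lower other genes. Of the called genes, 0% of those with other names and 13.46% of the predicted and small RNA genes were lower in run 2. This cannot decide the question, since in simulated data the run fit recovered 0% of differences of 2 log2 units. In addition, 79 called genes higher in run 2 had a mean under 1 FPKM in run 1. This explanation therefore stayed open. Transcript length may take part, since the called genes higher in run 2 had a median length of 0.05 times that of tested genes matched on mean expression, as a library or size selection step that kept short fragments in run 2 could give. No biological explanation was tested, and both runs of a day may hold different embryos.

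Other groupings of the same sets were counted for each fit across genes. For the contrasts between classes the real grouping alone gave its count, in 1 of 100 splits in Fev-high minus Neurog3-high (33 members, highest other 2), alpha-like minus Fev-high (9, highest other 1) and alpha-like minus beta-like (6, highest other 1), and in 1 of 35 in beta-like minus Fev-high (21, highest other 0). The classes came from clustering the same cells, so regrouped means were bound to differ less and these splits do not exclude chance. With the day as the unit these counts came to 17, 2, 0 and 1 members. For the slope over all cells (real 0, highest other 3) and the difference of slopes between classes (real 0, highest other 1) every grouping gives as many genes as a real count of 0, in 60 of 60 orders and 32 of 32 splits, so these counts say nothing about chance. For the runs 10 splits are too few for a share under 0.05, and 7 of them, the real one included, gave as many genes as the real one or more (98 higher and 14 lower in the real one, 255 genes in the highest other).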

How the results depend on the processing

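Alternatives that leave out the 3 early classes, the 2 sets low in GC-rich transcripts or clusters 7 and 8, that use E13.5 to E15.5 or E14.5 and E15.5 alone, that rescale without predicted genes, or that use stage means for shares or classes were chosen after seeing the data. No paired analysis was possible because the labels give no replicate number or animal that pairs cells or sets across days; classes were compared within sets, with the set as a block. Of 238 list means along stage recomputed with other settings, 219 stayed on their side of the threshold, 12 lost their call, 3 gained one and 4 reversed by their mean or by camera's direction. The mean had the other sign in 6 of the 219, all in lists that did not pass, in 2 of the 12 and in 1 of the 3. The cause of each change below was not tested, except that fewer sets or class means leave fewer residual degrees of freedom.

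Along stage over all cells, 0 genes passed in the reported fit, 1 with pseudocount 0.1, 3 with no run term, and 0 to 1 with a set left out. Among the lists, endocrine transcription factors turned with run 2 only (0.025) and over E13.5 to E15.5 (0.0072), where camera pointed down, and ribosomal proteins turned with run 2 only (0.057) and without the 3 early classes (0.20). In alpha-like cells 0 genes passed as reported, 5 with the mean of log values, 6 in run 1 only, 1 without the 2 sets low in GC-rich transcripts, 1 without clusters 7 and 8, and 0 to 1 with a set left out. In Neurog3-high cells 0% passed as reported, 1.0% with the mean of log values, 3.81% in run 1 only and 0.054% on stage means. The difference of slopes gave 0 as reported, 2 with the mean of log values, 1 on stage means and 0 to 1 with a set left out.

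List members past the test in Fev-high minus Neurog3-high were 33 as reported, 50 with rescaled cells, 16 with run-centred clustering, 17 on stage means and 13 to 34 with a set left out. In alpha-like minus Fev-high they were 9, with 4 for means of 10 cells or more, 26 with the mean of log values, 3 with no filter, 15 with rescaled cells, 2 on stage means and 0 to 12 with a set left out. In beta-like minus Fev-high they were 21, with 7 for means of 10 cells or more, 6 with no filter, 0 with run-centred clustering, 1 on stage means and 1 to 21 with a set left out. In alpha-like minus beta-like they were 6, with 13 for the mean of log values, 3 with no filter, 0 with run-centred clustering, 0 on stage means and 1 to 7 with a set left out, and lists past the test there were 1 as reported, 2 with the mean of log values, 3 with no filter, 2 with run-centred clustering and 1 to 3 with a set left out. Between runs 98 genes were higher and 14 lower as reported, and 28 genes passed with pseudocount 10, 57 with no filter and 9 with cells rescaled without predicted, small RNA and mitochondrial genes, which also left these out of the test.

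The slope of the insulin share stayed positive at 8.38 points per day outside the 3 early classes, 12.2 in run 1 only, 12.3 on stage means, 13.9 without the 2 sets low in GC-rich transcripts and 9.98 to 18.9 with a set left out, and passed in none of these except without E13.5 run 2. Only the first of these settings left enough arrangements for this share to pass on its own p, so not passing in the others says little. Without E12.5 the exact permutation p was 0.0417, where 0.0069 was possible. At thresholds of 1 or 100 FPKM and with cells of at least 300000 fragments it was 0.0028, the smallest possible. The ranges with a set left out were -0.49 to 2.77 for Gcg and 2.78 to 4.62 for Ghrl. The beta-like share passed with cells of at least 300000 fragments (11.2) and with run-centred clustering (11.7), where fewer tied values allowed a smaller p. As reported it could not pass on its own p. Of 236 recomputed share slopes 13 had the other sign, with neither value past the test. The number of sets and their spread limit what a count of 0 can show. Over all cells 31.3%, 91% and 97% of genes with simulated slopes of 1, 2 and 4 log2 units per day were recovered. For a slope of 1 it was 6% in Neurog3-high cells and 0% for the difference of slopes. In the data Ins2 (3.76 ± 0.57), Ins1 (2.87 ± 0.57) and Sst (2.58 ± 0.61) had slopes above 2 and did not pass. The simulated rates therefore do not show that real slopes of this size would be found. With cells of at least 300000 fragments the count over all cells was also 0.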

Other observations

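The shares by class given here were chosen after the classes were seen, and their differences were not tested.

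Neurog3 transcripts were also found outside the Neurog3-high class. At 10 FPKM or more they were in 90.6% of Neurog3-high cells (exact binomial interval 85.5 to 94.3%), 47.4% of Fev-high cells (36 to 59.1%), 24.5% of alpha-like cells (16.8 to 33.7%) and 21.9% of beta-like cells (13.1 to 33.1%). Acinar or tip-like cells held them in 19.8% (12.2 to 29.4%), against 2.4% (0.1 to 12.6%) of leukocyte-like cells with median depths of 555175 and 606416 fragments. These intervals treat cells as independent.

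Hormone transcripts were mixed within classes. Insulin transcripts at 10 FPKM or more were in 36.4% of alpha-like cells (27.4 to 46.1%) and 74% of beta-like cells (62.4 to 83.5%), with medians of 0 and 1365 FPKM. Of the 42 leukocyte-like cells 41 came from E11.5 and E12.5, so no background level was measured for the later days, when insulin transcripts were most abundant. Ppy was in 40.9% of alpha-like and 23.3% of beta-like cells, and Ghrl in 24.5% of alpha-like and 14.7% of Neurog3-high cells, where its mean was 5899 FPKM with a median of 0. With Leiden resolution 2, 17 cells formed a cluster with the ghrelin cell markers Ghrl, Irs4, Anpep and Acsl1, and run-centred clustering and 1000 variable genes gave such clusters of 29 and 27 cells. At the reported resolution these cells had no cluster of their own.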
